A study of Saccharomyces cerevisiae with 44 samples.

How the data were processed

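The series is RNA sequencing of the budding yeast Saccharomyces cerevisiae, strain W303, a standard laboratory background. Cultures were grown with 1 of 6 replication inhibitors or with the vehicle of that inhibitor. Per the labels, each of the 11 groups had 2 biological replicates (independent cultures) and each culture had 2 technical replicates, which makes 44 libraries of 22 cultures. The title and the characteristics of 1 CM library give it as the second technical replicate of culture 2 while its description gives the first, and the title was followed.

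The counts were made by the authors with featureCounts 1.6.0, per the file headers, as whole reads per annotated feature of the sacCer3 genome build, and they are not normalized. The command recorded in the file headers sets no strand option, no pair option and no option for reads that overlap several features. Reads were therefore counted without regard to strand, and a read that overlapped more than 1 feature was left out. The alignment file names in the file headers contain the words bowtie2, mskDup and non-redundant. Bowtie2 is also in the submitters' processing notes, while its version is not given in the sources used here. The names point to removal of duplicate reads before counting, a step that lowers the counts of abundant genes more in deeper libraries. The table has 6692 features, and 96.6% of their lengths are multiples of 3, so that lengths are coding lengths. Gene names were matched by systematic name to the RefSeq annotation of the R64 assembly. In all, 6008 features matched, and 6000 of these had the same coordinates in both. Coordinates below are those of the deposited tables.

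The authors' deposited tables of comparisons, 1 per treatment, hold DESeq2 log2 fold changes, p-values and adjusted p-values per gene, with treatment against its own vehicle. The mean signal per gene in those deposited tables was not used here. They were used only to set the number of genes past an adjusted p of 0.05 beside the number found here. All other values come from the counts.

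Counts were summed over the technical replicates of each culture, since the culture is the unit that was treated. P-values below therefore rest on 2 cultures per group, and the spread between cultures was shared over all groups. Genes were kept by filterByExpr of edgeR 4.0.16 (R 4.3.3; minimum count 10, minimum total 15), which left 6344 genes. Library sizes were scaled by TMM. A negative binomial model with 1 mean per group was fitted to all 22 cultures, and each contrast was tested with the quasi-likelihood F test of edgeR (robust), with Benjamini-Hochberg adjustment over the 6344 genes and a threshold of 0.05. The common biological coefficient of variation was 0.156, with 11 residual degrees of freedom and a median prior of 5.49. Standard errors of log2 fold changes are the fold change divided by the root of the F statistic. CPM were computed by edgeR from TMM-scaled library sizes and are given as the mean and SD of 2 cultures. Comparisons were the 6 treatments against their vehicles, HU against MMS, which share the C0 vehicle, and C0 against CD, which are water vehicles in 2 media.

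A set of 26 gene lists, the rule for naming genes, the tests and most alternatives were fixed before the data were examined. Lists were tested with camera of limma 3.58.1 on log CPM (prior count 2) with a preset correlation between genes of 0.01, with adjustment over the 26 lists of a comparison. Camera was also run with an estimated correlation, and fry was run as another alternative. With the estimated correlation 6 of the 87 list calls of all 8 comparisons held, namely the DNA damage regulon in HU, CPT and MTX, the M-G1 cluster in CPT, ergosterol in HU against MMS, and phosphate and alkaline pH in C0 against CD. All listed genes but PHR2 matched. The genes named for a treatment are the 6 largest rises and 6 largest falls past the threshold that lay on the same side in both cultures, with a mean of at least 10 CPM and a standard name. To these were added up to 3 members with the smallest p in the direction of each of up to 6 lists with the smallest camera p. RNR3, HUG1 and RNR1 were named in every treatment. Results of 2 single genes that the rule also named are not reported here. For the other 2 comparisons the 4 largest rises and falls were named by the first part of the rule. Features with a near-identical copy (390 features, at least 95% identity by BLAST 2.17.0 over at least 30% of the length) are called uncertain, since their reads can be split or lost. The same holds for 776 features that overlap another over at least 30% of their length, on either strand.

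Library totals ranged from 6.82 to 15.08 M counts. The procedure was tested on simulated counts drawn from the real means and spreads of the 6344 genes, with 200 genes changed. For HU against C0, 80.6% of genes changed 2-fold, 22.4% of those changed 1.5-fold and 95.5% of those changed 4-fold were called, with 9 of 6144 unchanged genes called. For DOX against CD the shares were 65.7%, 10.4% and 95.5%, with 2 unchanged genes called. In the 6 simulations of treatments no list was called by camera where none had been changed. Genes were drawn independently of one another, so this does not test the effect of correlation between genes on the list calls. Each gene was also drawn with the same spread in all groups. In the real counts the log2 difference between the 2 cultures of a group varied more over genes in some groups. Its SD was 0.51 in CA, 0.47 in AD and 0.46 in CPT, against 0.24 in CD. The simulations therefore do not test false calls in groups with a larger spread.

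Alternatives were RLE scaling, no composition scaling, the Wald test of DESeq2 1.42.0, no filter, a filter of 50 counts in 2 cultures, fits of only the groups compared or of only 1 medium, the 4 libraries as independent replicates, voom with the culture as a random block, the culture number as a block, leaving out each culture, an adjusted p of 0.01, and leaving out ribosomal, mitochondrial and transposon rows. Alternatives chosen after seeing the data were removal of an abundance trend between cultures and leaving out the shallower technical replicate of CPT culture 2.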

Results

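RNA sequencing was carried out on W303 yeast treated at IC50 doses with 6 agents that interfere with DNA replication. HU, MMS, CPT, MTX and DOX are usual field abbreviations of hydroxyurea, methyl methanesulfonate, camptothecin, methotrexate and doxorubicin, and the labels give the abbreviations only. HU at 50 mM and MMS at 0.002% were compared with water (C0), and CPT at 100 µg/mL with 1 N NaOH (CC), all in the rich medium YEPD. AD at 50 µg/mL was compared with 2% acetone (CA), DOX at 25 µg/mL with water (CD) and MTX at 150 µg/mL with 0.1 N NaOH (CM), all in SC, a synthetic medium. Each of the 11 groups held 2 cultures with 2 technical replicates each. Totals per library ranged from 10.99 to 14.37 M counts in C0, 9.87 to 14.34 in HU, 9.48 to 10.41 in MMS, 10.34 to 15.08 in CC and 6.82 to 11.54 in CPT. They ranged from 11.52 to 13.26 M counts in CA, 10.82 to 12.01 in AD, 10.79 to 12.9 in CD, 8.07 to 8.91 in DOX, 11.21 to 14.13 in CM and 10.94 to 12.81 in MTX. RNR3 and HUG1, followed in all treatments, were low in all 5 vehicles, with means between 10.9 and 12.9 CPM and between 0.373 and 0.637 CPM.

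**Figure D1:**
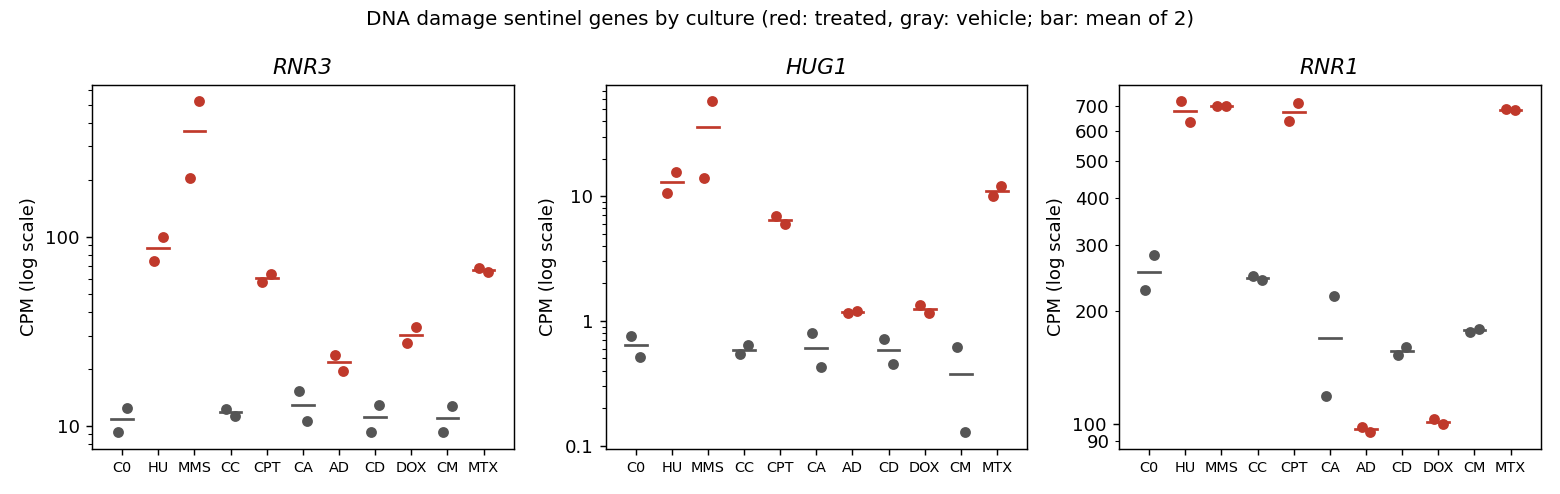
CPM (log scale) of RNR3, HUG1 and RNR1 in each culture of the 11 groups, with each treatment to the right of its vehicle, gray for vehicles, red for treatments and a bar at the mean of 2 cultures. HU, MMS, CPT and MTX cultures lie above their vehicles for all 3 genes, with mean RNR3 between 60.6 and 362 CPM against at most 12.9 CPM in vehicles.

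HU, an inhibitor of ribonucleotide reductase, raised the genes of that enzyme and of the checkpoint that controls it. RNR3 (YIL066C, sacCer3 chromosome IX, 238099 to 240708), the damage-inducible large subunit, went from 10.9 ± 2.17 CPM (SD, n = 2) in C0 to 87 ± 17.3 CPM in HU, a log2 fold change of 3 (SE 0.35; edgeR adjusted p = 0.000218). RNR2 (YJL026W, chromosome X, 392404 to 393603), the small subunit, rose from 194 ± 35.1 to 1020 ± 114 CPM (log2 fold change 2.39, SE 0.18). RNR4 rose by 1.61 (SE 0.15) and RNR1, the main large subunit, by 1.42 (SE 0.19) on the log2 scale. HUG1 (YML058W-A, chromosome XIII, 158760 to 158966), a small checkpoint-induced protein that binds the enzyme, rose from 0.637 ± 0.178 to 13 ± 3.49 CPM (log2 fold change 4.31, SE 0.59). In the list of the Mec1-Rad53-Dun1 DNA damage regulon 10 of 20 members rose and none fell. Adjusted over the list alone, 12 rose (median log2 fold change 0.58; camera adjusted p = 5.57e-14, and adjusted p = 0.00831 with an estimated correlation).

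Genes of the G1-S transition also rose in HU, 9 of 30 over all genes and 17 adjusted over the list alone (median 0.51; camera adjusted p = 9.69e-12, adjusted p = 0.139 with an estimated correlation). They included POL1 (log2 fold change 0.81, SE 0.11) and POL2 (0.67, SE 0.11), catalytic subunits of replicative DNA polymerases. Of 31 genes of Gcn4-dependent amino acid synthesis 10 rose, 14 adjusted over the list alone (camera adjusted p = 6.8e-09, adjusted p = 0.375 with an estimated correlation). LYS9 of lysine synthesis was at 1.5 (SE 0.14), HIS4 at 1.05 (SE 0.18) and ARG3 at 2.21 (SE 0.38). In the M-G1 cluster, which is expressed at the end of mitosis, 7 of 17 fell, and 11 fell and 1 rose adjusted over the list alone (median -0.69; camera adjusted p = 2.96e-08, adjusted p = 0.139 with an estimated correlation). The chitinase gene CTS1 changed by -1.25 (SE 0.16), and the daughter-specific genes DSE1 and DSE2 by -1.57 (SE 0.24) and -1.24 (SE 0.24). HO, the mating-type switching endonuclease, had the largest fall (-2.09, SE 0.29), and the amino acid permease DIP5 (-1.95, SE 0.4), SPS4 (-1.46), the proline permease PUT4 (-1.44) and MUM3 (-1.29) fell as well. The other large rises were ADE17 of purine synthesis (2.03, SE 0.52), BNA2 of NAD synthesis (1.83, SE 0.2), and DDI2 and DDI3 (1.91 each), which are near-identical copies and so uncertain. Among Hsf1 chaperones none of 20 was called over all genes in the fit without a block. Adjusted over the list alone 5 fell (camera adjusted p = 2.2e-05, adjusted p = 0.363 with an estimated correlation). MDJ1 was at -0.84, HSC82 at -0.38 and HSP82 at -0.93. In the Yap1 oxidative stress list GTT2 rose (1.09, SE 0.25), while AHP1 at 0.63 and OYE3 at 1.79 were not called in the fit without a block (camera adjusted p = 0.000172, adjusted p = 0.375 with an estimated correlation).

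In all, 226 of 6344 genes were called in HU by edgeR, 167 higher and 59 lower, of which 93 and 15 changed at least 2-fold. The authors' deposited table, made with DESeq2, has 1118 genes at an adjusted p under 0.05, and all 226 genes called here are among them. Leaving out C0 culture 1 or 2 gave 111 or 61 genes, and leaving out HU culture 1 or 2 gave 110 or 85. The genes named here for HU that were called stayed called in all 4 of these fits, the exceptions being ADE17, ARG3, DIP5, DSE2, GTT2, HIS4, MUM3, PUT4 and SPS4.

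MMS, which methylates DNA, raised damage-induced genes and lowered ergosterol and respiration genes. RNR3 rose from 10.9 ± 2.17 to 362 ± 223 CPM (SD, n = 2), a log2 fold change of 5.06 (SE 0.38; edgeR adjusted p = 6.46e-07), and HUG1 from 0.637 ± 0.178 to 35.7 ± 30.6 CPM (5.77, SE 0.6). Both MMS cultures lay above both C0 cultures, though they differed from one another more than in most groups. RNR2 rose by 2.32, RNR4 by 1.55 and RNR1 by 1.47. Of the damage regulon 9 of 20 rose and none fell, also 9 adjusted over the list alone (median 0.47; camera adjusted p = 3.37e-07, adjusted p = 0.058 with an estimated correlation). In the G1-S list 9 of 30 rose, 13 adjusted over the list alone (camera adjusted p = 1.89e-06, adjusted p = 0.514 with an estimated correlation), with POL1 at 0.6 and the cohesin gene SMC1 at 0.92. In the proteasome list 5 of 32 rose, both over all genes and adjusted over the list alone (camera adjusted p = 3.77e-05, adjusted p = 0.747 with an estimated correlation), among them RPN12 (1.14, SE 0.15), PRE1 (0.66) and SCL1 (0.73).

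The largest other rises in MMS included several genes known from anaerobic growth. TIR1 (YER011W, chromosome V, 175248 to 176012), a cell wall mannoprotein made without oxygen, rose from 2.53 ± 0.156 to 133 ± 52.1 CPM (5.72, SE 0.32; edgeR adjusted p = 2.51e-08). DAN1, of the same kind, rose by 5.37 (SE 0.54). ANB1, the anaerobic form of translation factor eIF5A, rose from 13.9 ± 3.53 to 372 ± 71.7 CPM (4.74, SE 0.41), and HES1, an oxysterol-binding protein, by 3.65 (SE 0.57). Ergosterol genes fell: 21 of 24 fell and 2 rose, the same numbers adjusted over the list alone (median -1.09; camera adjusted p = 3.5e-20, adjusted p = 0.058 with an estimated correlation). HMG1, the rate-setting reductase, went from 805 ± 120 to 145 ± 26.6 CPM (-2.48, SE 0.15), with ERG20 at -1.15 (SE 0.1) and ERG8 at -1.34 (SE 0.13). Respiration genes fell too, 16 of 35 and 17 adjusted over the list alone (median -0.77; camera adjusted p = 1.75e-12, adjusted p = 0.747 with an estimated correlation). CYC1, iso-1-cytochrome c, went from 79.7 ± 9.28 to 8.79 ± 0.572 CPM (-3.18, SE 0.34), COX13 changed by -1.82, COX5A by -2.35, QCR10 by -2.65, COX26 by -4.22 and the NADH dehydrogenase NDE1 by -3.23. PUT4 had the largest fall (-4.57, SE 0.34). In the Aft1 iron list 6 of 22 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0175, adjusted p = 0.967 with an estimated correlation). Those that fell included HMX1, heme oxygenase (-3.84, SE 0.37), the oxidase FET3 (-1.64) and the copper transporter CCC2 (-1.88).

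Of 683 genes called in MMS 385 were higher and 298 lower, 140 and 84 of them at least 2-fold, and the authors' deposited table has 1900. The rDNA share of counts was 1.865% to 2.28% in MMS libraries and 1.14% to 1.725% in C0, and MMS libraries were shallower. Leaving out C0 culture 1 or MMS culture 1 or 2 gave 394, 426 and 302 genes, and all genes named here for MMS stayed called in all 4 fits that left out 1 culture.

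HU and MMS were compared directly, because both used C0. The largest single differences included genes known from anaerobic growth, and the lists with the smallest camera p were ergosterol, respiration and Gcn4 amino acid synthesis. TIR1 was lower in HU by 4.61 (SE 0.3; edgeR adjusted p = 2.35e-07) on the log2 scale, at 5.47 ± 0.875 against 133 ± 52.1 CPM (SD, n = 2), and DAN1, ANB1 and HES1 were at -5.14, -4.07 and -3.8. PUT4, NDE1, HMX1 and QCR10 were higher in HU by 3.13, 3.12, 2.71 and 2.66. In HU 19 of 24 ergosterol genes were higher and 2 lower than in MMS, 22 and 2 adjusted over the list alone (camera adjusted p = 9.51e-26, and adjusted p = 0.046 with an estimated correlation). Of the respiration genes, 17 of 35 were higher, 21 adjusted over the list alone (camera adjusted p = 1.01e-18, adjusted p = 0.729 with an estimated correlation). Of 31 Gcn4 genes 7 were higher in HU, 12 adjusted over the list alone (camera adjusted p = 5.62e-09, adjusted p = 0.729 with an estimated correlation). RNR3 was lower in HU than in MMS (log2 difference -2.06, SE 0.33; edgeR adjusted p = 0.00127). HUG1 (-1.46, SE 0.46) and RNR1 (-0.05, SE 0.19) were not called. For the damage list as a whole camera gave an adjusted p of 0.394. A total of 287 genes were called, 153 higher in HU and 134 lower. Leaving out HU culture 1 or 2 gave 93 or 161 genes and leaving out MMS culture 1 or 2 gave 123 or 145, while all 8 named genes stayed called.

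**Figure D2:**
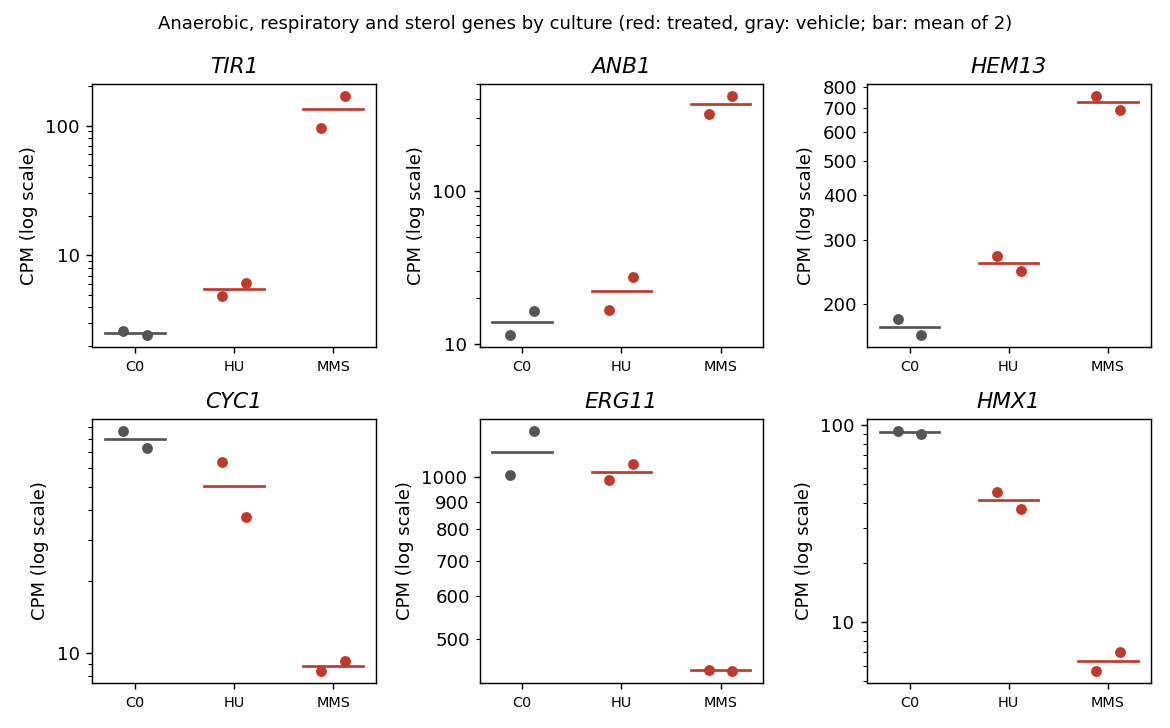
CPM (log scale) in each culture of C0 (gray), HU and MMS (red), with a bar at the mean of 2 cultures, for the anaerobic genes TIR1 and ANB1, the heme synthesis gene HEM13, the cytochrome gene CYC1, the sterol gene ERG11 and the heme oxygenase gene HMX1; HEM13 and ERG11 were chosen after their values were seen. MMS cultures lie above both other groups in the first 3 and below them in the other 3, for example TIR1 at 133 CPM on average against 5.47 in HU and 2.53 in C0.

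CPT, an inhibitor of topoisomerase I, raised the ribonucleotide reductase genes and lowered genes of cell separation. RNR3 rose from 11.8 ± 0.75 to 60.6 ± 4.67 CPM (SD, n = 2; log2 fold change 2.36, SE 0.34; edgeR adjusted p = 0.00119), and RNR2 by 2.11 (SE 0.18). RNR4 rose by 1.81 (SE 0.15), RNR1 by 1.47 (SE 0.19) and HUG1 from 0.589 ± 0.0677 to 6.47 ± 0.62 CPM. Of the damage regulon 11 of 20 rose, 13 adjusted over the list alone (median 0.75; camera adjusted p = 6.97e-17, and adjusted p = 0.00409 with an estimated correlation). In the M-G1 cluster 11 of 17 fell, and 14 fell and 1 rose adjusted over the list alone (median -1.59; camera adjusted p = 6.9e-22, and adjusted p = 0.00681 with an estimated correlation). CTS1 (YLR286C, chromosome XII, 708448 to 710136) went from 197 ± 8.62 to 45.1 ± 1.45 CPM (-2.12, SE 0.16), DSE1 changed by -2.56, EGT2 by -2.25, DSE2 by -2.21 and the glucanase DSE4 by -2.09. HO had the largest fall (-2.97, SE 0.3). This list fell further in CPT than in HU (median log2 difference 0.82 of HU minus CPT; camera adjusted p = 1.88e-20, and adjusted p = 0.0177 with an estimated correlation). No single gene differed between the 2 responses by edgeR, and no other tool was run on this difference. An unadjusted p under 0.05 was found for 151 genes, fewer than the share of 0.05 of 6344 genes that no difference would give on average.

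Of 8 core histone genes 5 fell in CPT, 8 adjusted over the list alone (median -0.72; camera adjusted p = 4.63e-11, adjusted p = 0.0586 with an estimated correlation), among them HHT1 (-0.74, SE 0.12), HTA2 (-1.01, SE 0.18) and HTA1 (-0.88, SE 0.16). In the G1-S list 6 of 30 rose, and 13 rose and 2 fell adjusted over the list alone (camera adjusted p = 5.35e-06, adjusted p = 0.367 with an estimated correlation), with POL1 at 0.57. In the proteasome list 3 of 32 rose, 5 adjusted over the list alone (PRE1 0.76, RPN12 0.72, SCL1 0.63; camera adjusted p = 5.44e-07, adjusted p = 0.375 with an estimated correlation). The other large rises were SHC1 of chitin synthesis in spores (1.68, SE 0.21), YRO2 (1.53, SE 0.27) and the cell wall gene PIR3 (1.49, SE 0.32). No respiration gene of 35 was called in the fit without a block (ATP14 0.74, CYT1 0.59, ATP15 0.68), and the list passed camera (adjusted p = 0.000581, adjusted p = 0.691 with an estimated correlation) but turned below 0 without CPT culture 2 or CC culture 1. In both groups culture 1 was lower than culture 2 in 24 glucose-repressed genes, with a median log2 difference of -0.66 in CC and -0.65 in CPT. The SD of that difference over all genes was 0.44 and 0.46. The low-affinity hexose transporter HXT1 was at 237 and 8.6 CPM in the CC cultures and 200 and 9.1 CPM in the CPT cultures, and the lactate transporter JEN1 at 41.2 and 340 CPM in CC and 49.7 and 164 CPM in CPT; both were chosen after their values were seen.

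A total of 178 genes were called in CPT by edgeR, 121 higher and 57 lower, 43 and 17 at least 2-fold, and the authors' deposited table has 735. Leaving out CC culture 1 or 2 gave 100 or 65 genes and leaving out CPT culture 1 or 2 gave 279 or 51. A fit of CPT and CC alone gave 29. Of the genes named here for CPT and called, HTA2, HUG1, PIR3, POL1, RPN12, SCL1 and YRO2 were lost in at least 1 fit that left out a culture.

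AD changed sulfur and proteasome genes, and the DNA damage regulon was not called as a list (2 of 20 rose, and 3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.296). MET3 (YJR010W, chromosome X, 456239 to 457774), which activates sulfate, rose from 150 ± 0.117 to 436 ± 28.6 CPM (SD, n = 2; log2 fold change 1.54, SE 0.25; edgeR adjusted p = 0.00467). MET1 of siroheme synthesis rose by 1.13 (SE 0.17) and MET14 by 0.97 (SE 0.15). In the sulfur and methionine list 8 of 22 tested members rose, and 13 rose and 1 fell adjusted over the list alone (median 0.59; camera adjusted p = 2.82e-08, adjusted p = 0.345 with an estimated correlation). In the proteasome list 8 of 32 rose and 1 fell, 23 and 1 adjusted over the list alone (median 0.4; camera adjusted p = 3.52e-13, adjusted p = 0.345 with an estimated correlation), with PUP1 at 0.56, PRE2 at 0.49 and RPT5 at 0.45. In the ergosterol list 2 of 24 rose, 10 adjusted over the list alone (camera adjusted p = 1.75e-05, adjusted p = 0.773 with an estimated correlation). ERG27 was at 0.53 and ERG4 at 0.6, while ERG7 at 0.47 was not called in the fit without a block. Of the Gcn4 list 3 of 31 rose, and 7 rose and 1 fell adjusted over the list alone (BNA1 0.85, TRP2 0.52, LYS1 0.85; camera adjusted p = 0.00335, adjusted p = 0.773 with an estimated correlation). The glutaredoxin GRX8 rose by 1.39 (SE 0.18), the formate dehydrogenase FDH1 by 1.49, NDJ1 by 1.11 and EMA19 by 1.06.

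INO1 (YJL153C, chromosome X, 134332 to 135933), the first enzyme of inositol synthesis, fell from 191 ± 0.966 to 46 ± 1.82 CPM in AD (-2.05, SE 0.19; edgeR adjusted p = 3.35e-05). The ammonium permease MEP2 (-1.68), RPL22B (-1.59), the amino acid permease AGP1 (-1.3), the gluconeogenic gene FBP1 (-1.39) and IMD2 of GTP synthesis (-1.33, uncertain because of near-identical copies) also fell. In the M-G1 list 2 of 17 fell, 5 adjusted over the list alone (camera adjusted p = 0.00393, adjusted p = 0.773 with an estimated correlation). SCW11 was at -1.16 and DSE2 at -0.97, while CTS1 at -0.51 was not called in the fit without a block. RNR1 fell from 169 ± 71.3 to 96.8 ± 2.42 CPM (-0.8, SE 0.19), while HUG1 (0.95, SE 0.67) was not called. RNR3 (0.74, SE 0.33) was not called in the fit without a block, but was called with the culture number as a block (0.75, edgeR adjusted p = 0.0294). The CA cultures differed from one another in 24 glucose-repressed genes, with a median log2 difference of culture 1 minus culture 2 of 0.97 (SD of all genes 0.51). The AD cultures differed in the same direction, at 0.49 (SD of all genes 0.47). JEN1, chosen after its values were seen, was at 1000 and 153 CPM in CA and 210 and 90 CPM in AD. Of the 25 genes of the induced environmental stress response none was called over all genes in the fit without a block. Adjusted over the list alone 1 rose (median -0.9, camera adjusted p = 0.00779, adjusted p = 0.773 with an estimated correlation). HSP42 was at -1.45, SOL4 at -1.53 and TPS2 at -1.18. The list turned above 0 without CA culture 1 or AD culture 2.

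A total of 199 genes were called in AD by edgeR, 128 higher and 71 lower, 23 and 24 at least 2-fold, and the authors' deposited table has 1120. Leaving out CA culture 1 gave 75 genes and leaving out AD culture 2 gave 10. A fit of AD and CA alone called 0 genes, with 646 at an unadjusted p under 0.05, while DESeq2 on all cultures called 428. Of the 24 named genes called, AGP1, GRX8, INO1, MET1, MET14 and RPL22B stayed called in all 4 fits that left out a culture.

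DOX, an intercalating inhibitor of topoisomerase II, had the largest number of genes called of the 6 treatments. Several heat-shock chaperones rose: HSP26 from 7.99 ± 1.2 to 116 ± 32.3 CPM (SD, n = 2; log2 fold change 3.86, SE 0.43; edgeR adjusted p = 9.01e-06). SSA4 (YER103W, chromosome V, 364589 to 366517) rose from 170 ± 18.7 to 1900 ± 386 CPM (3.48, SE 0.38) and SSA3 from 82.9 ± 1.27 to 723 ± 73.5 CPM (3.13, SE 0.21). Of 20 Hsf1 chaperones 10 rose and 2 fell, also adjusted over the list alone (median 0.57; camera adjusted p = 0.00757, adjusted p = 0.578 with an estimated correlation). In the proteasome list 29 of 32 rose and 1 fell, also adjusted over the list alone (median 0.78; camera adjusted p = 7.35e-13, adjusted p = 0.481 with an estimated correlation), with RPN1 at 1.49 (SE 0.1), PRE7 at 1.19 and RPT5 at 0.98. Of the Yap1 oxidative stress list 14 of 23 rose, 15 adjusted over the list alone (OYE2 1.02, CCP1 0.98, GLR1 0.98; camera adjusted p = 2.77e-05, adjusted p = 0.481 with an estimated correlation). In the sulfur list 12 of 22 rose and 2 fell, also adjusted over the list alone (MET10 2.4, CYS3 1.43, MET1 1.61; camera adjusted p = 0.000487, adjusted p = 0.481 with an estimated correlation). PHO92 (3.17), SDH9 (3.16) and the spore wall gene GAS2 (3.07) were the other large rises.

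All 8 core histone genes fell in DOX, also adjusted over the list alone (median -1.01; camera adjusted p = 4.02e-05, adjusted p = 0.481 with an estimated correlation), with HTB2 at -1.24 (SE 0.18), HTA1 at -1.09 (SE 0.16) and HHF1 at -0.93, the last uncertain because of a near-identical copy. In the M-G1 list 11 of 17 fell, also adjusted over the list alone (PIR1 -1.92, EGT2 -1.72, SCW11 -1.88; camera adjusted p = 0.00182, adjusted p = 0.481 with an estimated correlation). AGP1 fell from 958 ± 55.1 to 101 ± 16.9 CPM (-3.25, SE 0.17; edgeR adjusted p = 1.06e-08), and RGI2 (-3.82, SE 1.04), TMA10 (-3.72, SE 0.95), ROQ1 (-2.95), JEN1 (-2.9, SE 0.92) and the hexokinase HXK1 (-2.89) fell as well. RNR3 rose to 30.4 ± 4.16 from 11.1 ± 2.6 CPM (1.45, SE 0.34; edgeR adjusted p = 0.00309), RNR1 fell (-0.62, SE 0.19), and HUG1 was not called (1.06, SE 0.71). Transcripts of the mitochondrial genome rose, 6 of 8 both over all genes and adjusted over the list alone (COX3 0.86, with COX1 and COB at 0.83 each but overlapping other features; camera adjusted p = 0.00757, adjusted p = 0.578 with an estimated correlation). The share of mitochondrial counts was 0.537% to 0.574% in DOX libraries against 0.323% to 0.362% in CD. That of rDNA was 2.093% to 2.387% against 1.328% to 1.496%, and DOX libraries were shallower.

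A total of 2615 genes were called in DOX by edgeR, 1332 higher and 1283 lower, 408 and 432 at least 2-fold, and the authors' deposited table has 3874. The share called higher was 50.9%, and 43.6% without composition scaling. Both scalings make fold changes relative to the other genes of a library. The split therefore depends on the scaling and cannot show whether mRNA as a whole rose or fell. Without CD culture 1 the count was 1722, and of the genes named here for DOX and called, JEN1, RGI2, RNR1 and TMA10 were lost in at least 1 fit that left out a culture.

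MTX, an inhibitor of dihydrofolate reductase, raised purine and one-carbon genes, the ribonucleotide reductase genes and cell wall genes. ADE17 (YMR120C, chromosome XIII, 507502 to 509280), which acts with a folate cofactor late in purine synthesis, rose from 64.8 ± 3.27 to 1300 ± 158 CPM (SD, n = 2; log2 fold change 4.33, SE 0.57; edgeR adjusted p = 0.000232). MTD1, a methylenetetrahydrofolate dehydrogenase, rose from 33.2 ± 2.95 to 216 ± 0.492 CPM (2.7, SE 0.23). In the purine and one-carbon list 11 of 26 rose and 5 fell, 13 and 5 adjusted over the list alone (camera adjusted p = 0.0125, adjusted p = 0.674 with an estimated correlation). In the damage regulon 14 of 20 rose, and 14 rose and 1 fell adjusted over the list alone (median 0.9; camera adjusted p = 1.35e-09, and adjusted p = 0.0351 with an estimated correlation). RNR2 rose by 2.66 (SE 0.18), RNR3 by 2.6 (SE 0.35), RNR4 by 1.81 and the kinase gene DUN1 by 1.87 (SE 0.18). RNR1 rose by 1.95 (SE 0.2) and HUG1 from 0.373 ± 0.347 to 11 ± 1.43 CPM. In the G1-S list 10 of 30 rose and 1 fell, 16 and 1 adjusted over the list alone (CDC21, thymidylate synthase, 1.14; SMC1 0.99; camera adjusted p = 1.8e-06, adjusted p = 0.492 with an estimated correlation).

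Cell wall genes rose in MTX, 14 of 21 both over all genes and adjusted over the list alone (median 0.74; camera adjusted p = 8.42e-09, adjusted p = 0.198 with an estimated correlation), with PIR3 at 3.57 (SE 0.34), SED1 at 1.78 (SE 0.19) and CRH1 at 1.44 (SE 0.14). Of 35 respiration genes 9 rose, 10 adjusted over the list alone (SDH3 1.29, ATP14 1.26, SDH4 1.41; camera adjusted p = 4.15e-06, adjusted p = 0.674 with an estimated correlation). The stress genes HSP12 (2.87) and HSP26 (2.79) and GND2 of the pentose phosphate pathway (2.78) also rose. Among Hsf1 chaperones 7 of 20 fell, 9 adjusted over the list alone (HSC82 -0.48, FES1 -0.98, BTN2 -2.22; camera adjusted p = 0.00218, adjusted p = 0.674 with an estimated correlation). Of 28 ribosome biogenesis genes 3 fell, also adjusted over the list alone (GAR1 -0.64, NOP7 -0.68, RPA190 -0.53; camera adjusted p = 0.00368, adjusted p = 0.674 with an estimated correlation). The largest falls were HSP30 (-2.53, SE 0.46), SFG1 (-2.45, SE 0.21), SPS4 (-2.37), HO (-2.3), BTN2 and MUM3 (-1.87). In MTX 1259 genes were called by edgeR, 688 higher and 571 lower, 223 and 72 at least 2-fold, and the authors' deposited table has 2489. Leaving out CM culture 1 or 2 gave 562 or 544 genes, and leaving out MTX culture 1 or 2 gave 739 or 513. Of the genes named here for MTX, BTN2, FES1, GAR1, HSC82, HSP12, NOP7 and RPA190 were lost in at least 1 of these fits.

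**Figure D3:**
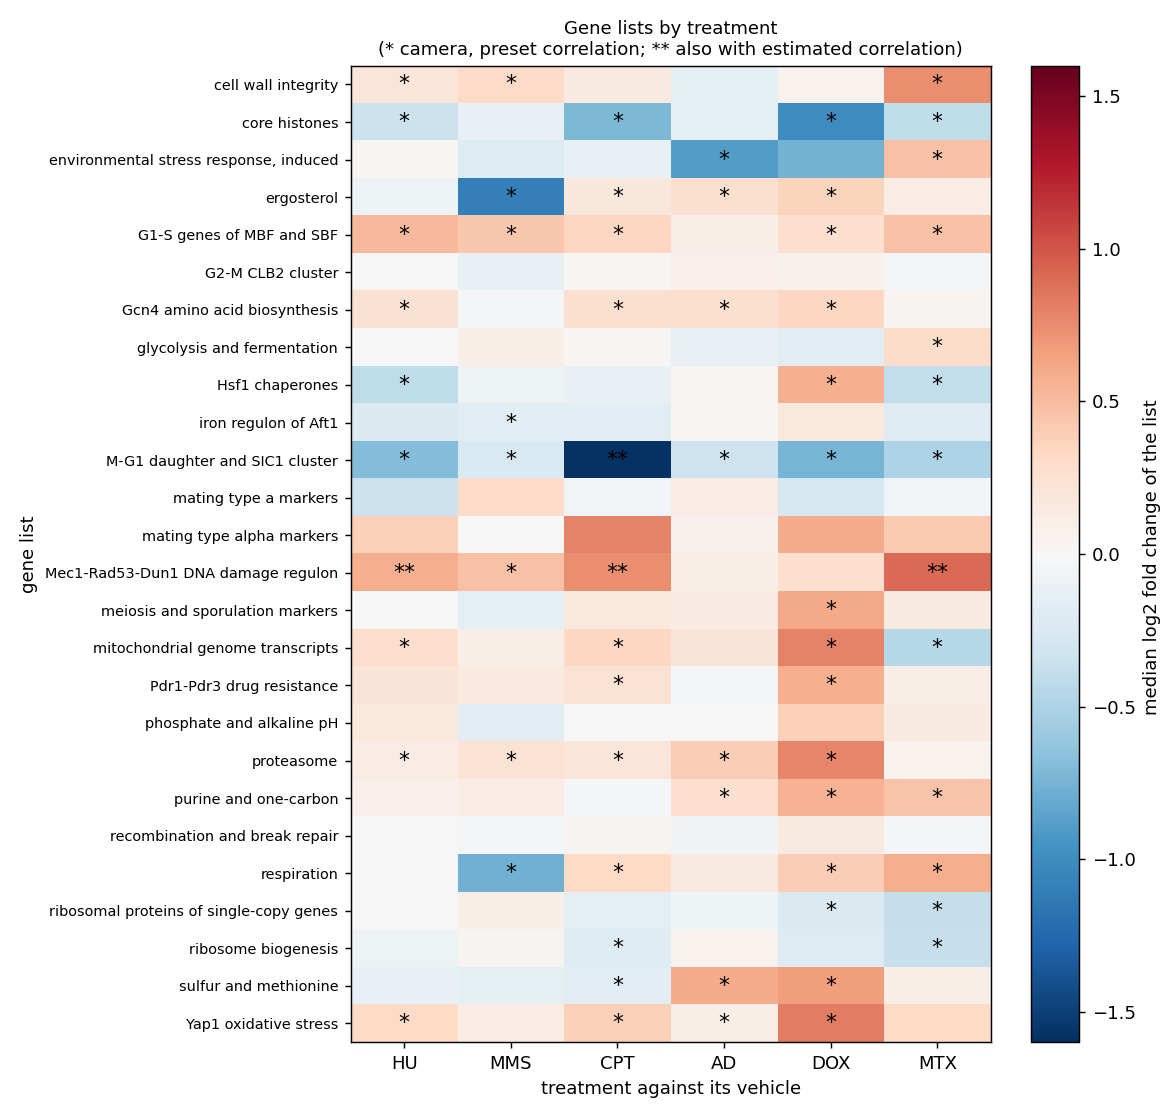
Median log2 fold change (color) of the 26 gene lists (rows) in the 6 treatments against their vehicles (columns), with 1 star where camera called the list with the preset correlation and 2 stars where it also did with an estimated correlation. The DNA damage regulon is starred in HU, MMS, CPT and MTX, with medians of 0.58, 0.47, 0.75 and 0.9, and the M-G1 list in CPT has the lowest median, -1.59.

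The vehicles C0 and CD, both water, differed in medium, and also in the set of experiments to which they belong. Phosphate genes were higher in YEPD. SPL2 (YHR136C, chromosome VIII, 374654 to 375100), an inhibitor of low-affinity phosphate uptake, was at 49.7 ± 0.511 CPM in C0 and 0.579 ± 0.138 in CD (SD, n = 2; log2 difference 6.42, SE 0.23; edgeR adjusted p = 2.31e-11). The phosphate transporter PHO89 was higher by 5.39 (SE 0.43). The acid phosphatases PHO11 and PHO12, near-identical copies and so uncertain, were higher by 6.2 and 6.16. In the list of phosphate and alkaline pH genes 14 of 19 were higher in C0, also adjusted over the list alone (median 2.08; camera adjusted p = 1.43e-15, and adjusted p = 0.00345 with an estimated correlation). The genes lowest relative to SC were JEN1 (-3.01, SE 0.92), HSP12 (-2.7, SE 0.63), ARG1 of arginine synthesis (-2.53, SE 0.33) and the carnitine carrier CRC1 (-2.39, SE 0.64). Respiration genes were lower in C0, 21 of 35 and 30 adjusted over the list alone (camera adjusted p = 8.82e-12, adjusted p = 0.741 with an estimated correlation). In all 1274 genes were called, 711 higher in C0 and 563 lower. The count was 219 without C0 culture 2, 533 without CD culture 1 and 234 without CD culture 2, and JEN1, HSP12 and CRC1 were lost in at least 1 of these fits.

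The 6 responses were compared across the 6344 genes, which are not independent replicates. Fold changes of HU and CPT had the highest Pearson r (0.71), followed by AD and DOX (0.64), CPT and MTX (0.62) and HU and MTX (0.61), all of which have separate vehicles. This order depends on single cultures, since r of HU and CPT was 0.53 without CPT culture 2 and 0.54 without CC culture 1. MMS had an r of 0.37 with CPT and 0.36 with MTX, and AD and DOX had between 0.14 and 0.28 with the other 4 treatments. HU and MMS, with the shared vehicle C0, had an r of 0.57. With all 3 groups simulated from the C0 means, so that only the shared control links them, r was 0.484 on average. The observed covariance of 0.113 exceeded the simulated 0.036 by 0.077. With HU set against 1 C0 culture and MMS against the other, r was 0.42 and 0.25. The calls of HU and CPT shared 60 higher genes where independent lists would share 3.2, and 22 lower genes where 0.5 would be shared. AD and DOX shared 119 higher genes (26.9 for independent lists) and 61 lower genes (14.4). HU and MMS shared 98 higher genes (10.1) and 27 lower genes (2.8), part of which may come from the shared vehicle and from transposon features that are near-identical copies.

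The difference of responses was also tested gene by gene with edgeR. HU, MMS and CPT were in YEPD, and AD, DOX and MTX were in SC. Differences between a treatment in YEPD and 1 in SC cannot be told apart from effects of the medium or the set of experiments. The log2 fold change of RNR1 in HU lay above that in AD by 2.22 (SE 0.27; adjusted p = 0.00209) and above that in DOX by 2.04 (SE 0.27; adjusted p = 0.00016). For RNR3 the MMS response exceeded that of CPT by 2.7 (SE 0.47; adjusted p = 0.00406) and that of MTX by 2.46 (SE 0.47; adjusted p = 0.00632). The damage regulon differed between CPT and AD (median difference 0.9; camera adjusted p = 1.08e-09, and adjusted p = 0.0405 with an estimated correlation). The ergosterol list was lower in MMS than in CPT (median difference -1.12; camera adjusted p = 1.34e-31, and adjusted p = 0.0217 with an estimated correlation). The M-G1 list was lower in CPT than in MTX (median difference -0.82; camera adjusted p = 9.05e-15, and adjusted p = 0.0455 with an estimated correlation). Between AD and DOX 335 genes differed, and the proteasome list was lower in AD (median difference -0.35; camera adjusted p = 1.42e-07, adjusted p = 0.371 with an estimated correlation).

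**Figure D4:**
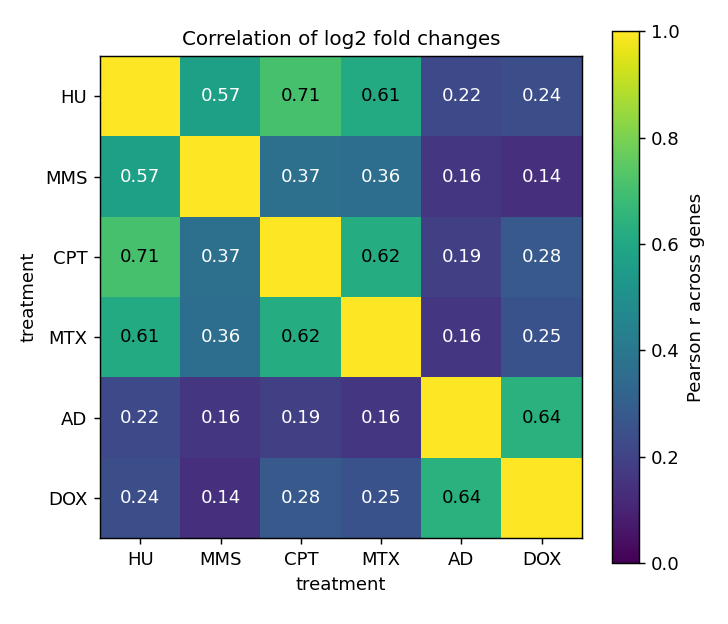
Pearson r across 6344 genes of the log2 fold changes (color and number) for each pair of the 6 treatments (rows and columns). HU, CPT and MTX share values of 0.61 to 0.71, AD and DOX 0.64, and the other pairs with AD or DOX lie between 0.14 and 0.28.

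Genes called higher in HU, MMS, CPT and MTX together numbered 40, of which 10 have near-identical copies and are not independent genes, and those called lower in all 4 numbered 8. HU and MMS share C0, so no number for independent lists is set beside these. Among the 40 were RNR1, RNR2, RNR3, RNR4, HUG1, DUN1, RAD54 and RDH54 of recombination, POL1 and CDC45, and among the 8 were DSE1 and AMN1, a daughter-specific regulator of mitotic exit; these examples were chosen after their values were seen. Of the 26 lists camera called 10 in HU, 8 in MMS, 13 in CPT, 8 in AD, 15 in DOX and 13 in MTX. Markers of mating type a and alpha, the recombination and repair list and the G2-M CLB2 cluster were not called by camera in any of the 6 treatments. These are tests of whole lists, and single members could still change. In DOX the alpha marker STE3 was at 8.24 and 10.1 CPM, against 1.12 and 1.04 in CD. The a marker MFA2 was at 20.5 and 14.3 CPM, against 52.5 and 45 in CD; both were chosen after their values were seen.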

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

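The test of the shared medium and the test of the link between depth and abundance were chosen only after the result was seen.

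In 33 tests, of 11 groups of 4 libraries for depth, rDNA share and mitochondrial share, 3 found a library far from the other 3, and chance gives about 1 in 20. The second technical replicate of HU culture 1 had 14.34 M counts, with the others of HU at 9.87 to 10.55. The first technical replicate of C0 culture 1 had a mitochondrial share of 0.274%, with the others at 0.204% to 0.209%. The second technical replicate of CM culture 2 had 0.384%, with the others at 0.314% to 0.325%.

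Several genes known from anaerobic growth, such as TIR1, DAN1 and ANB1, were high in both MMS cultures, and the respiration and sterol lists were low. An abundance trend between libraries is argued against: with the trend removed the sterol list kept a median log2 fold change of -1.07 (-1.09 before). A difference in growth stage stays open, since the median of 24 glucose-repressed genes was -0.337 (SE 0.16), between the bounds set for and against it. A list of 10 further hypoxic genes had a median of 0.44 (camera adjusted p = 0.000482, adjusted p = 0.111 with an estimated correlation). The 3 called members were TIR3, FET4 and HMG2, while OLE1 was at -0.22, PDR11 at 0.11 and SUT1 at 0.39. The list was meant to hold genes not looked at before, but HMG2 also belongs to the ergosterol list tested above. It is therefore not wholly independent of the pattern it was set to check. The median met the bound set in advance for a program of low oxygen or low heme. The same list was, however, also higher in C0 than in CD, 2 water vehicles in different media. Its median there was 0.445, with 4 called higher (camera adjusted p = 0.00435, adjusted p = 0.249 with an estimated correlation). A shift of this size therefore also arose without MMS, and the list is weak evidence for such a program. Whether MMS itself or the aeration of these 2 cultures lowered oxygen or heme was not tested, so the biological reading remains a hypothesis.

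AD and DOX, with different vehicles, gave similar fold changes. The shared SC medium is argued against as the whole cause: MTX was also in SC, and r of MTX with DOX lay below r of AD with DOX by at least 0.26 in all fits that left out 1 culture. Vehicle cultures further on in growth than treated ones were weighed by regressing out the differences between the 2 cultures of CA and of CC, in which glucose-repressed genes vary; r was 0.65 after and 0.64 before. Those differences took up only 7.1% and 4.5% of the variance of the AD and DOX fold changes, so removing them could hardly lower r. The regression therefore cannot decide on growth stage, which stays open. The 24 glucose-repressed genes had a median log2 fold change of -0.627 in AD (camera adjusted p = 0.00257, adjusted p = 0.589 with an estimated correlation), with 1 called lower. In DOX their median was -0.112, with 5 called higher and 5 lower. A response common to the compounds may explain the similarity but was not tested.

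Abundant genes took a slightly larger share of the counts in shallower libraries. Over the 22 pairs of technical replicates the slope of the log ratio on abundance, from -0.039 to 0.033 over 5351 genes of at least 10 CPM, was related to the log ratio of depth with Pearson r = -0.56 (permutation p = 0.0039) and Spearman rho = -0.6 (permutation p = 0.0037). Without the 2 pairs farthest from the median r was -0.49. These pairs come from the same cultures, so biology is not a likely source, and duplicate removal, named in the file headers, is a candidate explanation. No biological explanation was tested.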

How the results depend on the processing

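Removal of the abundance trend, and the count without the shallower technical replicate of CPT culture 2, were chosen after seeing the data.

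Apart from those followed in every treatment, named genes were chosen for cultures on the same side, or for a small p in the direction of a list. That choice left little room for a turn in direction, so the next result says little about other genes. No named gene turned in direction under any alternative run on it, out of 196 named gene values. Calls were lost by 37 of these in the fit of only the groups compared, 15 in the fit of only 1 medium, 31 at an adjusted p of 0.01, 10 with the abundance trend removed, 3 with RLE, 1 without composition scaling and 2 without ribosomal, mitochondrial and transposon features. Leaving out each culture in turn lost 138 calls over all these fits. Of the 87 list calls, run with the other scalings, set tests, the block, the fit of only the groups compared and without each culture, those that turned are named below. RLE or no composition scaling, no filter, the stricter filter, removal of ribosomal, mitochondrial and transposon rows and removal of the abundance trend kept each count within 1.5 times of its value, as did leaving out the shallower CPT library (196). Counting the 4 libraries as independent replicates gave 999 genes for HU, 1735 for MMS, 910 for CPT, 1268 for AD, 2475 for MTX, 1201 for HU against MMS and 2618 for C0 against CD. DESeq2 gave 359 for HU, 318 for CPT, 428 for AD and 437 for HU against MMS, and voom with the culture as a random block gave 395, 353, 539 and 491. The fit of only the groups compared gave 29 for CPT, 0 for AD (646 at an unadjusted p under 0.05 by edgeR), 2261 for MTX and 586 for HU against MMS, and the fit of only 1 medium 130 for HU, 414 for MMS, 62 for CPT and 151 for HU against MMS. An adjusted p of 0.01 left 95, 338, 56, 33, 1671 and 602 genes in HU, MMS, CPT, AD, DOX and MTX, 137 for HU against MMS and 433 for C0 against CD. Apart from the stricter threshold and the change of replicate unit, the cause was not tested.

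Leaving out 1 culture at a time, where the lone culture is assumed to vary like other groups, gave 61 to 111 genes for HU, 302 to 517 for MMS, 51 to 279 for CPT, 10 to 243 for AD, 1722 to 1859 for DOX, 513 to 739 for MTX, 93 to 161 for HU against MMS and 219 to 1332 for C0 against CD. The lowest counts came without C0 culture 2, MMS culture 2, CPT culture 2, AD culture 2, CD culture 1, MTX culture 2, HU culture 1 and C0 culture 2. Single lists gained or lost their calls between these fits, and those that turned in direction follow. In CPT the mean log2 fold change of the mitochondrial list turned to -0.06 and of the Yap1 list to -0.01 without CPT culture 2, with 0.86 and 0.56 without CPT culture 1. That of respiration turned to -0.15 without CPT culture 2 and -0.08 without CC culture 1, with 0.86 without CPT culture 1. In AD the stress list turned to 0.17 without CA culture 1 and 0.04 without AD culture 2, with -1.53 without CA culture 2.

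With the culture number as a block, edgeR called 552 genes for HU, 1239 for MMS, 537 for CPT, 892 for AD, 2056 for MTX, 741 for HU against MMS and 2174 for C0 against CD. It also called 13 named values that were not called without it. They are MDJ1 (adjusted p = 0.0363), HSP82 (0.0124), AHP1 (0.00488) and OYE3 (3.5e-05) in HU, and the respiration genes ATP14 (0.00809), CYT1 (0.0114) and ATP15 (0.017) in CPT. In AD they are RNR3 (log2 fold change 0.75; adjusted p = 0.0294), TPS2 (0.00117), SOL4 (0.00259), HSP42 (0.00769), ERG7 (0.0132) and CTS1 (0.0493). The labels do not say that a number marks a shared day. Deviations of equal-numbered cultures from their group means correlated across genes at 0.34, 0.06, 0.49, 0.71, 0.16 and -0.24 for HU, MMS, CPT, AD, DOX and MTX with their vehicles, 0.12 for HU with MMS and -0.14 for C0 with CD.

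An estimated correlation kept 6 of 87 list calls and fry made 52. Restricted to genes called in at least 1 of the 2 treatments, r was 0.67 for HU and MMS, 0.85 for HU and CPT and 0.77 for AD and DOX. With C0 split it was 0.42 and 0.25 for HU and MMS. Leaving out 1 culture gave 0.45 to 0.66, 0.53 to 0.67 and 0.51 to 0.65 for the 3 pairs. With 2 cultures per group, simulated 1.5-fold changes were called for 10.4% to 32.8% of genes, so many changes of that size would be missed at this design.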

Other observations

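All values in this part were chosen after the data were seen. Transposon reading frames were called higher in large numbers in HU, MMS, DOX and MTX. Of 50 tested rows 42 rose in HU, 43 in MMS, 10 in CPT, 41 in DOX and 43 in MTX, and 2 in AD, and 2 fell in each of HU, MMS, AD, DOX and MTX, with medians of 1.01, 1.47, 0.63, 0.9, 0.95 and 0.59 on the log2 scale. These rows are near-identical copies of one another, so that single rows are uncertain and their number does not count independent genes.

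Some genes were called in nearly all treatments. FRD1, a soluble fumarate reductase, and RDH54, a DNA translocase of recombination, were called higher in all 6, with log2 fold changes of 0.66 to 1.2 and 0.52 to 0.91. A total of 34 genes were higher in at least 5 treatments, of which 12 have near-identical copies and are not independent genes. They included TOP2, the topoisomerase II gene, at 0.88 in HU, 1.04 in MMS, 0.83 in CPT, 0.91 in DOX and 0.61 in MTX, with 0.42 in AD not called. PHO92, a reader of methylated RNA, was called higher in all but MMS (0.75), at 2.41 in HU, 1.59 in CPT, 2.3 in AD, 3.17 in DOX and 2.79 in MTX. Of 13 genes lower in at least 5 treatments, 2 have near-identical copies, and AMN1, DSE1, DSE2 and SCW11 belong to the M-G1 list. C0 is shared by HU and MMS, so part of these overlaps may not be independent; r between HU and MMS was 0.42 and 0.25 in the 2 ways of splitting C0.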
